A study of Medicago truncatula with 12 samples.

How the data were processed

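Roots of composite Medicago truncatula plants (line A17) with a 35S::MtCLE35 or a 35S::GUS construct were profiled without rhizobia and at 11 dpi with Sinorhizobium meliloti, in 12 libraries that form 4 groups of 3. Per the labels' protocols, total RNA was extracted and libraries were made with a MACE-Seq kit, which reads fragments near the 3' ends of transcripts. The submitters' processing notes name HISAT2, a read aligner, and StringTie, a transcript assembler and quantifier. Their versions, their settings, the genome build and the way reads were turned into counts are not given in the sources used here. The authors deposited 1 table of estimated counts for the whole series, with 52715 loci and 12 columns, 1 per library. All 12 columns matched a sample by its label. The values are whole numbers, so rounding left them as they were. Without a stated strand setting, reads of a locus and of an overlapping or antisense locus cannot be told apart, and loci with near-identical copies are uncertain.

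Each identifier stood for 1 locus (52715 distinct identifiers without their suffix, 0 of them repeated), so loci were tested as deposited. Of these 20781 had no counts in any library. The table held 132 plastid loci, 193 mitochondrial loci, 85 whose identifier starts with an s and 10 with identifiers of another kind, which held 0.0435% of all counts and stayed in the tests. The name table used here lists 39590 genes of another annotation, and 0 of the identifiers matched it. Gene names, product texts and coordinates were therefore not used here, MtCLE35 was not looked up by name, and the gene lists and product families fixed before the data were examined could not be applied.

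Library totals were 4869004, 3874903 and 2868406 counts in uninoculated GUS roots, 3127554, 3880719 and 2748459 in uninoculated MtCLE35 roots, 2752379, 6043031 and 4429275 in GUS roots at 11 dpi and 3556259, 2857726 and 7054495 in MtCLE35 roots at 11 dpi (replicates 1 to 3). At these totals, 3 counts over the 3 libraries of a group, the floor used for loci at 0, correspond to 0.227 to 0.292 CPM. Floors cover counting error and nothing else. A count of 0 in this table is not always a low level: 854 values of 0 stood beside at least 20 counts in each of the other 2 libraries of the same group. No pair of replicates agreed within sampling noise, with chi-square values per degree of freedom of 7.17 to 13.6 over loci, so all 12 libraries were counted separately.

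Counts were analysed with edgeR 4.0.16 in R 4.3.3. Loci were kept by filterByExpr with the group as factor, which left 21173, and libraries were scaled by TMM. A quasi-likelihood model (glmQLFit with robust estimation) with 1 mean per group was fitted to all 12 libraries, which share an estimate of the spread, and 5 comparisons were tested with glmQLFTest: MtCLE35 against GUS without rhizobia and at 11 dpi, 11 dpi against uninoculated roots in each root type, and their interaction. P-values were adjusted by the Benjamini-Hochberg method over all loci of a comparison, with a threshold of 0.05. The common biological coefficient of variation was 0.277. CPM values use the TMM-scaled totals. Sets of loci were tested with camera and fry of limma 3.58.1, and log2 CPM values for principal components, correlations and set medians used a prior count of 2. Directions are given relative to TMM, and the other scalings tried moved the median log2 fold change of all loci by at most 0.071 from its TMM value (upper quartile, MtCLE35 against GUS at 11 dpi). Neighbouring loci and other resampling tests were run in Python 3.11.15 with SciPy 1.17.1.

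The rule for naming loci was fixed before the data were examined: without gene names, up to 2 identifiers per direction and comparison, the largest absolute log2 fold changes among called loci with a mean of at least 5 CPM in the higher group and no overlap between the 3 libraries of each group. Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, other scalings, other filters, fits of 2 groups, a replicate block, stricter thresholds, counts thinned to the smallest library and each library left out in turn. Alternatives chosen after seeing the data left out identifiers of another format, left out the loci raised or lowered in GUS roots from the TMM factors, left out 2 libraries that lie apart on components 2 and 3, left out loci with an isolated 0, and tested lists of loci called in the other 6 libraries.

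The test was tried on simulated counts drawn from the means and spread of the 21173 loci, with 200 loci of at least 5 CPM changed in uninoculated MtCLE35 roots. It recovered 56 of the 200 at a 2-fold change, with 1 false call, and 161 at a 4-fold change, with 6 false calls. The direction was right for each recovered locus. Shared controls were assessed with 20 simulations of unchanged groups. Whether libraries with the same replicate number belong together, and what a block on that number changes, is given with the effects of the processing.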

Results

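Transcript levels were measured in transgenic roots of composite Medicago truncatula plants of line A17, in which transformed roots grow on an untransformed shoot. The roots carried either a 35S::MtCLE35 construct, which drives a peptide gene of the CLE family from a constitutive promoter, or a 35S::GUS construct, a reporter used as the control. CLE peptides are secreted signals, some of which restrict nodule number in legumes. Roots were taken without rhizobia on nitrogen-free medium or at 11 days post inoculation (dpi) with Sinorhizobium meliloti, the nitrogen-fixing partner of this legume. Each of the 4 groups had 3 libraries made by MACE-seq, which counts fragments near the 3' ends of transcripts. Libraries held 2748459 to 7054495 counts over 52715 loci, and 21173 loci had enough counts to be tested. The labels do not say whether the 3 libraries of a group came from separate plants, so p-values measure the spread between these libraries, which may in part be technical. Loci are named by the identifiers of the table, which give the chromosome, because these were not paired with gene names here. Coordinates and gene parts were not used here. Loci with 0 counts in a whole group are given fold changes as lower bounds, which cover counting error only. Isolated values of 0 also stood in 712 loci where the other 2 libraries of the group were well covered. No named locus was among these, which follows in large part from how both were defined. A group at 0 in all 3 libraries could not be counted there, and the naming rule bars a 0 in the higher group. This absence therefore says nothing on the values of 0 behind the lower bounds.

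GUS roots at 11 dpi stood apart from the other 3 groups. On the first principal component of log2 CPM, which held 41% of the variance, they lay at 126 ± 19.0 (SD, n = 3). Uninoculated GUS roots lay at -45.8 ± 2.38, uninoculated MtCLE35 roots at -35.9 ± 8.71 and MtCLE35 roots at 11 dpi at -43.9 ± 6.38 (SD, n = 3 each). Correlations of log2 CPM between libraries of GUS roots at 11 dpi and libraries of any other group were 0.727 to 0.814. Between libraries of the other 3 groups they were 0.859 to 0.931, which overlapped the 0.894 to 0.930 found within groups.

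**Figure D1:**
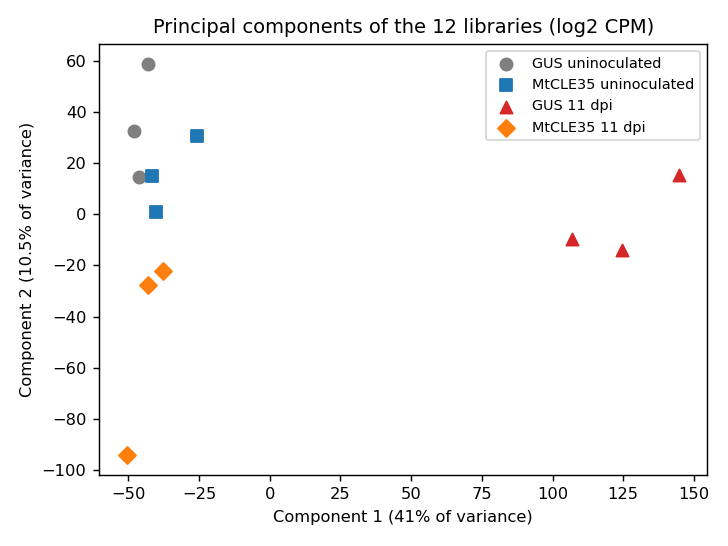
Positions of the 12 libraries on the first (x axis, 41% of variance) and second (y axis, 10.5% of variance) principal components of log2 CPM, with 1 point per library and a marker for each group. The 3 libraries of GUS roots at 11 dpi lie at the right, and the other 9 lie between -50.6 and -25.9 on the first component.

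The comparison of inoculated with uninoculated GUS roots measured the response to rhizobia in control roots. After inoculation 1239 loci rose and 350 fell among the 21173 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). A group of 492 of the raised loci, called inoculation-specific loci here and defined after the data were seen, had at most 3 counts summed over the 3 uninoculated GUS libraries. Their median level in GUS roots at 11 dpi was 26.6 CPM, with a range of 2.21 to 1280 CPM. Together the inoculation-specific loci took 2.50% ± 0.746 of the counts in GUS roots at 11 dpi (SD, n = 3). The highest was MtrunA17Chr3g0100421.6 on chromosome 3, at 1280 CPM ± 524 (SD, n = 3; 15842 counts) against 0 counts in uninoculated GUS roots. Set against a floor of 3 counts over the group, this locus was at least 4987-fold higher (edgeR adjusted p = 0.0035). MtrunA17Chr4g0032721.6 on chromosome 4 rose from 0 counts to 456 CPM ± 208 (SD, n = 3), at least 1776-fold (edgeR adjusted p = 0.0087). The first call ended without GUS 11 dpi replicate 2 (adjusted p = 0.0502; 5.03e-05 to 0.0502 over 26 alternatives), and the second without GUS 11 dpi replicate 1 and with limma-voom (7.71e-05 to 0.0756).

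Another 683 raised loci were already expressed at 1 CPM or more in uninoculated GUS roots, and their median log2 fold change was 1.09. All 1239 raised loci together took 10.2% ± 0.848 of the counts at 11 dpi and 3.76% ± 0.237 without rhizobia (SD, n = 3 each). The 350 loci that fell did so by less, with a median log2 fold change of -0.87 and median levels of 49.1 CPM without rhizobia and 24.4 CPM at 11 dpi. MtrunA17Chr5g0437961.10 fell from 11.0 CPM ± 1.92 (SD, n = 3) to 0 counts, at least 46.3-fold (edgeR adjusted p = 0.00854). MtrunA17Chr4g0050361.12 fell from 7.71 CPM ± 1.39 (SD, n = 3) to 0 counts, at least 32.4-fold (edgeR adjusted p = 0.0333), and this call was lost with limma-voom and without any one of the 6 GUS libraries or uninoculated MtCLE35 replicate 1 (adjusted p 1.85e-04 to 0.102 over 26 alternatives). No locus of the plastid (38 tested) or mitochondrial (32 tested) genome was among the raised or fallen loci. Among 53 tested loci whose identifier starts with an s, a form not explained in the sources used here, 28 were raised and 19 inoculation-specific. All 85 loci of this form, tested or not, took 0.446% of the counts in GUS roots at 11 dpi and 0.191% in uninoculated GUS roots. They took 0.167% in MtCLE35 roots at 11 dpi, and they may share reads with overlapping loci.

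The share of inoculation-specific loci differed between chromosomes. Chromosome 1 held 35 of them among 3077 tested loci (1.14%) and chromosome 8 held 32 among 2619 (1.22%), against 2.47% to 2.88% on the other 6 chromosomes. Two-sided Fisher exact tests against the remaining loci gave adjusted p of 2.43e-06 and 9.29e-05 over 13 classes of identifiers, and 4.79e-17 for the loci whose identifier starts with an s. These tests treat loci as independent, while inoculation-specific loci lay next to each other more often than by random placement, so these p are too small. The count of calls in GUS roots rested in part on single libraries. It was 897 without GUS 11 dpi replicate 1, 919 without GUS 11 dpi replicate 2 and 975 without uninoculated GUS replicate 1, and 327 loci were inoculation-specific without GUS 11 dpi replicate 2. The 350 fallen loci were 147, 159 and 149 in these 3 cases, 170 without GUS 11 dpi replicate 3, 211 without uninoculated GUS replicate 2 and 589 by DESeq2.

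**Figure D2:**
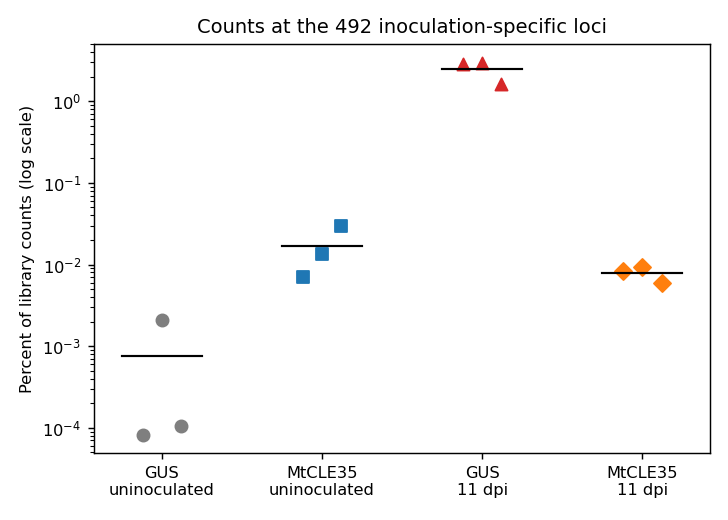
Share of each library's counts at the 492 inoculation-specific loci (y axis, percent, log scale) in the 4 groups (x axis), with 1 point per library and a bar at the mean of 3. These loci were chosen as raised in GUS roots at 11 dpi with at most 3 counts in uninoculated GUS roots, so the 2 GUS groups differ by construction. MtCLE35 roots at 11 dpi lie at 0.00788% on average, a share that includes MtrunA17Chr2g0325381.4, against 2.50% in GUS roots.

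The same comparison in MtCLE35 roots measured how these roots responded to rhizobia. Among the 21173 tested loci 6 rose and 3 fell (edgeR), with 2789 loci at an unadjusted p below 0.05. DESeq2 called 548 loci and limma-voom 8, and the edgeR count was 2 without uninoculated MtCLE35 replicate 3 and 4 without MtCLE35 11 dpi replicate 1. Without uninoculated MtCLE35 replicate 3 and MtCLE35 11 dpi replicate 2 together it was 2, with 0 of the 9 loci among them. The inoculation-specific loci held 0.00788% ± 0.00176 of the counts in MtCLE35 roots at 11 dpi and 0.0167% ± 0.0116 in uninoculated MtCLE35 roots (SD, n = 3 each). Among them was MtrunA17Chr2g0325381.4, which alone had 488 counts in MtCLE35 roots at 11 dpi and 426 in uninoculated ones, so it weighs on both shares. Of the 492 loci, 465 had at most 3 counts summed over the 3 MtCLE35 libraries at 11 dpi and 398 over the 3 uninoculated ones. The name inoculation-specific therefore refers to GUS roots alone. MtrunA17Chr3g0100421.6 and MtrunA17Chr4g0032721.6 had 0 counts in all 6 MtCLE35 libraries. MtrunA17Chr7g0218271.8 on chromosome 7 rose in both root types, from 14.7 CPM ± 3.35 to 46.0 CPM ± 3.13 in MtCLE35 roots (SD, n = 3 each; log2 fold change 1.64 ± 0.20 SE, edgeR adjusted p = 0.0153) and from 4.36 CPM ± 1.03 to 38.7 CPM ± 5.46 in GUS roots (SD, n = 3 each). In MtCLE35 roots its call was lost without uninoculated MtCLE35 replicate 2 or 3, or without that replicate 3 and MtCLE35 11 dpi replicate 2 together (adjusted p 5.50e-09 to 0.172 over 26 alternatives). MtrunA17Chr7g0263981.4 had 0 counts in 9 libraries and 56.5 CPM ± 5.77 in MtCLE35 roots at 11 dpi (SD, n = 3), at least 193-fold above uninoculated MtCLE35 roots (edgeR adjusted p = 0.00474; 3.33e-04 to 0.0586 over 24 alternatives, the highest without MtCLE35 11 dpi replicate 2 and uninoculated MtCLE35 replicate 3 together). MtrunA17Chr3g0126411.12 fell from 15.5 CPM ± 3.12 to 3.63 CPM ± 0.577 (SD, n = 3 each; log2 fold change -2.09 ± 0.26 SE, edgeR adjusted p = 0.0153), a call lost without MtCLE35 11 dpi replicate 3, uninoculated MtCLE35 replicate 3, or the latter and MtCLE35 11 dpi replicate 2 together (adjusted p 0.0109 to 0.151 over 24 alternatives). MtrunA17Chr8g0353801.14 fell from 24.4 CPM ± 1.11 to 10.1 CPM ± 1.35 (SD, n = 3 each; edgeR adjusted p = 0.042). Its call was lost in 13 of 24 alternatives (adjusted p 0.0345 to 0.386), among them those without any one of the 6 MtCLE35 libraries, GUS 11 dpi replicate 1 or 2, or uninoculated GUS replicate 3. DESeq2 called 6 of the 9 loci and gave no adjusted p, and so no call, for MtrunA17Chr7g0263981.4, MtrunA17Chr3g0126411.12 and MtrunA17Chr8g0353801.14 (unadjusted p = 1.72e-16, 7.18e-10 and 2.71e-07), which is why 24 alternatives are counted for these.

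Loci expressed without rhizobia and changed in GUS roots were compared as sets with the response of MtCLE35 roots, which shares no library. Their medians in MtCLE35 roots had the direction seen in GUS roots, a difference that passed with a preset correlation and not with an estimated one. The 350 loci that fell in GUS roots had a median log2 fold change of -0.177 in MtCLE35 roots, and 68.9% of them were lower. The 683 expressed loci that rose in GUS roots had a median of 0.146, and 66.9% were higher. All 1239 raised loci together had a median of 0 with 40.5% higher, and as a set they did not pass in MtCLE35 roots (camera adjusted p = 0.2, 0.95 with an estimated correlation, fry 0.612). Loci without counts in MtCLE35 roots were taken as not higher, so the remainder were not all lower. Of the inoculation-specific loci 388 had at most 3 counts in each MtCLE35 group. The sets of 350 and 683 loci passed limma's camera test against the other loci in MtCLE35 roots with the preset correlation of 0.01 (adjusted p = 2.80e-07 and 1.78e-06). With an estimated correlation the adjusted p was 0.0503 for each set, and by fry, which tests whether a set moves one way on balance, it was 0.0139 for each. The raw camera p of the fallen set was 0.47 without uninoculated GUS replicate 3. Of the 1589 loci called in GUS roots, 47 passed in MtCLE35 roots when adjusted over the list alone, 44 of them in the same direction (22 higher, 22 lower). This count was 183 by DESeq2 with the list of its own calls (144 in the same and 39 in the opposite direction) and 9 without MtCLE35 11 dpi replicate 2 and uninoculated MtCLE35 replicate 3 together, a choice made after seeing the data. It was 11 and 27 without uninoculated MtCLE35 replicates 3 and 2, 15 without either MtCLE35 11 dpi replicate 2 or 3, and 19 without GUS 11 dpi replicate 3. Over all 21173 loci the log2 fold changes of the 2 root types correlated across loci at r = -0.0419 (Spearman's rho = 0.094), over the 1589 loci called in GUS roots at r = -0.23 (rho = -0.142), and loci are not independent replicates. The 1589 include the 492 inoculation-specific loci, with a median log2 fold change of 5.57 in GUS roots and 0 in MtCLE35 roots. The negative value over this list therefore does not show opposed responses.

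**Figure D3:**
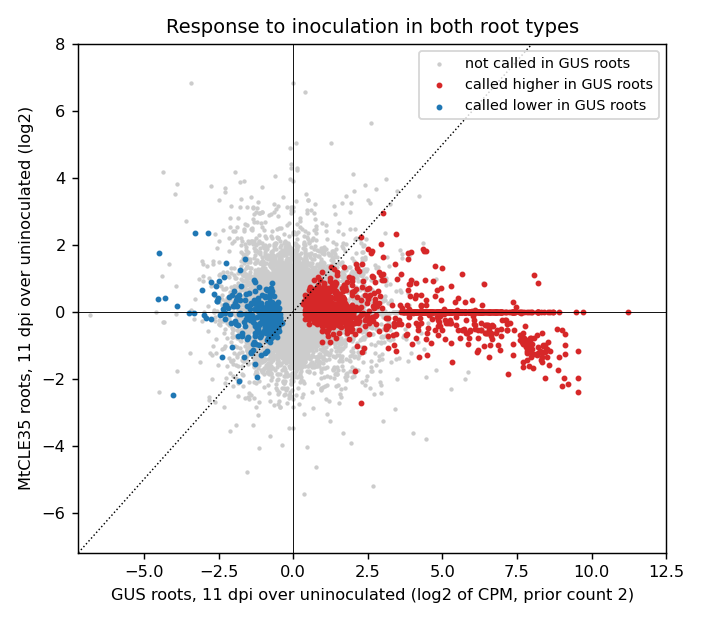
Log2 fold change of CPM at 11 dpi over uninoculated roots, with a prior count of 2, in GUS roots (x axis) and in MtCLE35 roots (y axis), with 1 point per tested locus and a dotted line where both are equal. The loci raised in GUS roots (red) extend along the horizontal line at 0, and the loci that fell in GUS roots (blue) have a median of -0.177 on the y axis.

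The interaction of construct and inoculation tested whether the response differed between the root types. It was called for 109 loci (edgeR), negative for 96 and positive for 13. Of the 96 loci with a negative interaction 94 had risen in GUS roots, and of the 13 with a positive interaction 10 had fallen there. The interaction holds the GUS response with a minus sign and uses the same GUS libraries, so part of this match follows by construction. MtrunA17Chr5g0438201.4 was at 133 CPM ± 21 in GUS roots at 11 dpi, 1.59 CPM ± 1.38 in uninoculated MtCLE35 roots and 0 counts in the other 2 groups (SD, n = 3 each; edgeR adjusted p = 0.0139). MtrunA17Chr4g0064831.4 was at 187 CPM ± 39.8 in GUS roots at 11 dpi, 1.11 CPM ± 1.19 in uninoculated MtCLE35 roots and 0 counts in the other 2 groups (SD, n = 3 each; edgeR adjusted p = 0.0199). MtrunA17Chr5g0425971.10 went the other way, from 84.1 CPM ± 37.1 to 25.6 CPM ± 2.85 on inoculation of GUS roots and from 18.5 CPM ± 4.02 to 56.4 CPM ± 17.7 in MtCLE35 roots (SD, n = 3 each; interaction 3.34 ± 0.44 SE on the log2 scale, edgeR adjusted p = 0.00795; 6.65e-10 to 0.0665 over 25 alternatives, the highest without MtCLE35 11 dpi replicate 2 and uninoculated MtCLE35 replicate 3 together). MtrunA17Chr1g0171011.8 went from 17.1 CPM ± 2.25 to 5.82 CPM ± 2.49 in GUS roots and from 8.01 CPM ± 3.15 to 29.3 CPM ± 16.7 in MtCLE35 roots (SD, n = 3 each; edgeR adjusted p = 0.0308). Its call was lost in 10 of 25 alternatives (adjusted p 3.46e-05 to 0.1), 7 of which left out 1 library. For neither MtrunA17Chr5g0425971.10 nor MtrunA17Chr1g0171011.8 was the rise in MtCLE35 roots itself called. Of the 13 loci with a positive interaction 1 was called there. Without rhizobia MtrunA17Chr5g0425971.10 was called lower in MtCLE35 than in GUS roots (log2 fold change -2.19, edgeR adjusted p = 0.0307). Of 25 alternatives 6 ended the calls of MtrunA17Chr5g0438201.4 (8.53e-09 to 0.0973) and MtrunA17Chr4g0064831.4 (1.16e-09 to 0.0948), among them limma-voom and those without uninoculated MtCLE35 replicate 2 or 3, GUS 11 dpi replicate 1, or the 2 libraries that lie apart (MtCLE35 11 dpi replicate 2, uninoculated MtCLE35 replicate 3). A negative interaction was called for 5.08% of the 492 inoculation-specific loci and 9.24% of the other 747 raised loci by edgeR, for 1.83% and 5.76% by limma-voom, and for 54.1% and 37.8% by DESeq2, which called 987 loci in all. The count of 109 was 39 without uninoculated MtCLE35 replicate 3, 50 without GUS 11 dpi replicate 1, 61 and 71 without MtCLE35 11 dpi replicates 3 and 2, and 212 without uninoculated GUS replicate 3 (88 positive and 124 negative). It was 61 by limma-voom and 23 (1 positive, 22 negative, 20 of them among the 109) without MtCLE35 11 dpi replicate 2 and uninoculated MtCLE35 replicate 3 together.

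Inoculated MtCLE35 roots were compared with inoculated GUS roots to measure the effect of the construct in the presence of rhizobia. In MtCLE35 roots 760 loci were lower and 209 higher (edgeR), and with upper quartile scaling 714 were lower and 335 higher. The lower loci had a median log2 fold change of -4.90, or -6.08 with the 462 loci that had 0 counts in MtCLE35 roots placed at their bound. Of the 492 inoculation-specific loci 454 were lower. MtrunA17Chr3g0100421.6 was at least 5645-fold lower (edgeR adjusted p = 0.00414; 0.0623 without GUS 11 dpi replicate 2, the highest of 26 alternatives, whose lowest was 5.29e-05). MtrunA17Chr4g0033101.4 was at 849 CPM ± 211 in GUS roots (SD, n = 3) and 0 counts in MtCLE35 roots, at least 3742-fold lower (edgeR adjusted p = 0.0053). The 209 higher loci differed less, with a median log2 fold change of 1.03 and median levels of 53.6 CPM in MtCLE35 and 25.4 CPM in GUS roots. MtrunA17Chr7g0263981.4 was at least 238-fold higher (edgeR adjusted p = 9.02e-05). MtrunA17Chr4g0020031.32 was at 9.65 CPM ± 4.29 (SD, n = 3) against 0 counts, at least 40.6-fold higher (edgeR adjusted p = 0.0104; 5.09e-06 to 0.129 over 26 alternatives, lost with limma-voom and without MtCLE35 11 dpi replicate 2 and uninoculated MtCLE35 replicate 3 together), and lay at 3.55 CPM ± 1.91 in uninoculated GUS roots.

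Of the 760 lower loci 661 had risen on inoculation of GUS roots, where independent lists of these sizes would share 44.5. Both comparisons use the GUS 11 dpi libraries, so part of the excess may come from these. Of the 760 loci 98.0% were higher at 11 dpi than without rhizobia in GUS roots, against 80.0% in simulations of unchanged groups, and the covariance of the 2 sets of log2 fold changes was -1.25 against -0.116 simulated. Of the 209 higher loci 22 had fallen on inoculation of GUS roots (3.45 for independent lists). The count of calls was 450 without GUS 11 dpi replicate 1, 595 without GUS 11 dpi replicate 2, 591 without MtCLE35 11 dpi replicate 2 and 545 without MtCLE35 11 dpi replicate 3. The 209 higher loci were 30, 84, 41 and 51 in these 4 cases, 123 without GUS 11 dpi replicate 3, 138 without uninoculated MtCLE35 replicate 1, 322 in a fit of the 2 groups alone, 441 by DESeq2 and 62 (of 610 in all) without MtCLE35 11 dpi replicate 2 and uninoculated MtCLE35 replicate 3 together.

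Without rhizobia, 7 loci were higher and 8 lower in MtCLE35 than in GUS roots (edgeR), with 2123 loci at an unadjusted p below 0.05. DESeq2 called 416 loci and limma-voom 12. MtrunA17Chr2g0325381.4 on chromosome 2 had 0 counts in uninoculated GUS roots and 42.8 CPM ± 10.7 in uninoculated MtCLE35 roots (SD, n = 3), at least 167-fold higher (edgeR adjusted p = 0.00532). At 11 dpi it was at 41.9 CPM ± 18.8 in MtCLE35 and 2.21 CPM ± 1.53 in GUS roots (SD, n = 3 each). The call without rhizobia was lost with limma-voom, and the adjusted p ran from 1.68e-11 to 0.295 over 26 alternatives. MtrunA17Chr7g0218271.8, which inoculation raised in both root types, was already higher in uninoculated MtCLE35 roots (log2 fold change 1.78 ± 0.23 SE, edgeR adjusted p = 0.0127), a call lost with limma-voom, in a fit of the 2 groups alone and without uninoculated GUS replicate 1 or 2 (adjusted p 3.96e-06 to 0.109 over 26 alternatives). MtrunA17Chr1g0205081.14 was at 76.1 CPM ± 11.2 in uninoculated GUS roots, 14.9 CPM ± 2.44 in uninoculated MtCLE35 roots, 14.1 CPM ± 2.86 in GUS roots at 11 dpi and 15.2 CPM ± 6.13 in MtCLE35 roots at 11 dpi (SD, n = 3 each; log2 fold change -2.34 ± 0.27 SE without rhizobia, edgeR adjusted p = 0.00532). MtrunA17Chr3g0129671.2 was at 23.1 CPM ± 1.14 in uninoculated GUS roots and 3.98 CPM ± 1.77 in uninoculated MtCLE35 roots (SD, n = 3 each; log2 fold change -2.56 ± 0.30 SE, edgeR adjusted p = 0.00532; 2.21e-09 to 0.0572 over 26 alternatives, the highest without MtCLE35 11 dpi replicate 2 and uninoculated MtCLE35 replicate 3 together).

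**Figure D4:**
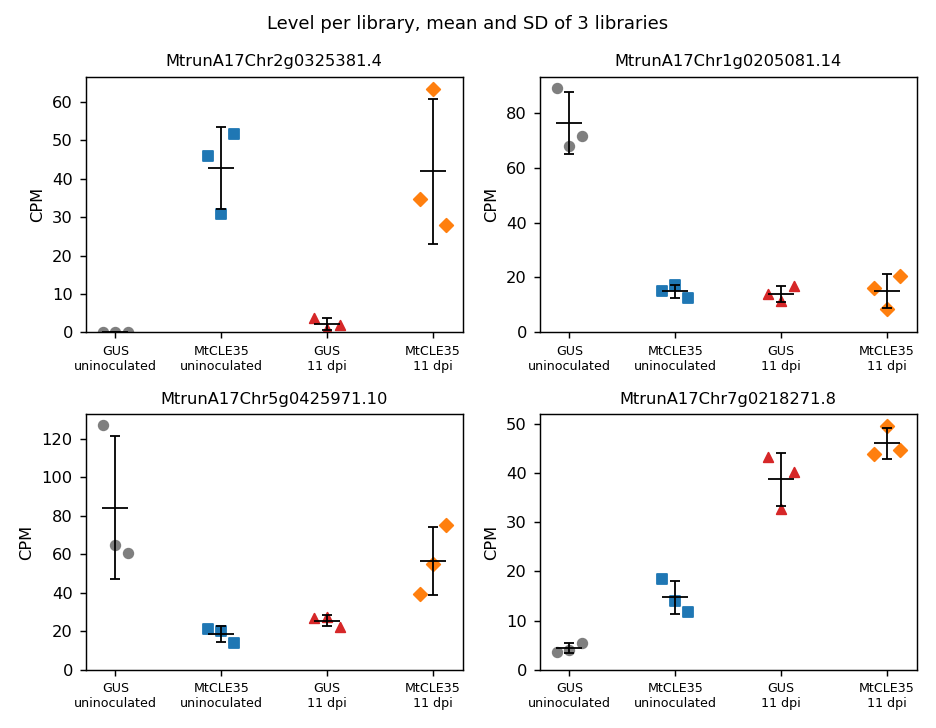
Levels in CPM (y axes, from 0) of 4 named loci in the 4 groups (x axes), with 1 point per library and the mean and SD of 3 libraries in black. MtrunA17Chr2g0325381.4 lies at 42.8 and 41.9 CPM in the MtCLE35 groups and at 0 and 2.21 CPM in the GUS groups, and MtrunA17Chr1g0205081.14 is highest in uninoculated GUS roots.

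Of these 15 loci 14 had the same sign in inoculated GUS roots relative to uninoculated ones, and 11 were called there. The 2 comparisons share the uninoculated GUS libraries, and the 15 largest changes in simulations of unchanged groups had the same sign for 13 loci on average (11 to 15). Over all loci the covariance of these log2 fold changes was 0.269, against 0.106 simulated (0.1 to 0.113). Their correlation was r = 0.349 against 0.496 simulated. The simulated groups lack the response to inoculation, whose variance lowers r, so the lower r does not offset the covariance. The covariance lay above all 20 simulations, but whether this reflects a likeness beyond the shared libraries was not tested. The effect of MtCLE35 without rhizobia and its effect at 11 dpi, which share no library, correlated across loci at r = -0.065 (Spearman's rho = 9.76e-04). Of the 969 loci called at 11 dpi, 18 passed without rhizobia when adjusted over the list alone, 14 of them in the same direction, and 75 by DESeq2 with the list of its own calls, 41 in the same and 34 in the opposite direction. Over the 969 loci the correlation was r = -0.183 (rho = -0.227). This does not show opposed effects, since the 760 loci lower at 11 dpi had a median log2 fold change of 0 without rhizobia. The 18 became 8 without MtCLE35 11 dpi replicate 3 or GUS 11 dpi replicate 1, 9 without GUS 11 dpi replicate 3, 28 without MtCLE35 11 dpi replicate 1 and 30 without uninoculated MtCLE35 replicate 1. The count of 15 loci changed to 64 without uninoculated GUS replicate 3 (11 higher and 53 lower), 29 without uninoculated MtCLE35 replicate 1, 9 without GUS 11 dpi replicate 1, 8 without uninoculated MtCLE35 replicate 3 and 7 without uninoculated GUS replicate 1.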

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

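The interaction test, the splits of the libraries, thinning and the RLE and upper quartile scalings were planned, and the test of the next locus was chosen before its result was seen. Reading thinning and scaling as tests of an explanation, TMM without the loci called in GUS roots, the tests of carry-over and counting noise, and the set tests were chosen only after the results were seen.

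The response to inoculation differed between MtCLE35 and GUS roots for 109 loci by the interaction test (edgeR), among them the 4 named loci MtrunA17Chr1g0171011.8 (adjusted p = 0.0308), MtrunA17Chr5g0425971.10 (0.00795), MtrunA17Chr5g0438201.4 (0.0139) and MtrunA17Chr4g0064831.4 (0.0199). With 3 libraries per group no test for a single far value was made, although MtCLE35 11 dpi replicate 2 and uninoculated MtCLE35 replicate 3 lay apart on principal components 2 and 3. Among 100 groupings of the 12 libraries, 1, the real one, gave as many loci for the interaction, and the highest of the others gave 63. Regrouping mixes GUS and MtCLE35 libraries of the same state, which differed at 969 loci at 11 dpi, and so widens the spread within groups. These groupings stand for no effect of the construct at all and not for a missing interaction, so they do not exclude chance for this count. For the other comparisons the 10 splits of 6 libraries are too few for a share under 0.05: the real split gave 1589 loci for inoculation of GUS roots (highest other 2), 9 for inoculation of MtCLE35 roots (3), 969 for MtCLE35 against GUS at 11 dpi (2) and 15 without rhizobia (2), so in each case 1 split gave as many.

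By edgeR, inoculation changed 9 loci in MtCLE35 roots and 1589 in GUS roots, and the interaction was called for 109. Lower depth of the MtCLE35 libraries is argued against, since thinning every library to the smallest total left 15 calls in MtCLE35 roots and 1483 in GUS roots. A shift of the scaling by the abundant inoculation-induced transcripts is argued against as well, since other scalings moved the median log2 fold change of all loci by at most 0.071. No difference between MtCLE35 roots at 11 dpi and uninoculated ones is argued against in part. With GUS roots 2 raised and 3 fallen loci were shared (0.351 and 0.0496 for independent lists). For the fallen set and the raised expressed set fry gave an adjusted p of 0.0139 each. Without regard to direction fry gave 1.68e-08 and 6.02e-08. The explanation stays open, because the fallen set had an adjusted p of 0.0503 by camera with an estimated correlation. Without the 2 libraries that lay apart 2 loci were called, with 0 of the 9 among them. That fit has fewer libraries in each MtCLE35 group, so calls may be lost through lower power, and it decides nothing here. In it MtrunA17Chr7g0263981.4 and MtrunA17Chr3g0126411.12 had log2 fold changes of 10.9 and -2.09. MtrunA17Chr7g0218271.8 and MtrunA17Chr8g0353801.14 had 1.46 and -1.14. A biological effect of the construct on the response, which the design names, may account for the pattern and was not separated from a difference in the number of infected plants.

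Uninoculated MtCLE35 replicate 3 held traces of the inoculation-specific transcripts, at 0.0134% of its counts when the loci were chosen without the library examined. Replicates 1 and 2 were at 0.00396%, with 104 of 124 counts at 1 locus, and 0.00183%, below the 0.00315% of uninoculated GUS replicate 2. The group means were 0.0064% ± 0.00616 here and 0.00135% ± 0.00161 in uninoculated GUS libraries (SD, n = 3 each). This choice drops loci with over 3 counts summed over the other libraries outside GUS roots at 11 dpi. Transcripts that 2 replicates share can thus be lost, which may lower these shares. Over all 492 inoculation-specific loci, MtrunA17Chr2g0325381.4 included, uninoculated MtCLE35 replicates 1 to 3 held 0.00713%, 0.01335% and 0.02958% of their counts. Carry-over from GUS 11 dpi libraries may be the source: in 2 of the 3 uninoculated MtCLE35 libraries the counts followed the GUS 11 dpi level across loci (one-sided permutation p = 0.046 for replicate 2 and 1e-05, the smallest these permutations can give, for replicate 3), while replicate 1 gave p = 0.99 and MtCLE35 11 dpi replicate 2, with 7 counts at 1 locus, gave p = 0.041. Counts fell on fewer loci than proportional carry-over would reach, 83 against 192 in replicate 3, 26 against 57 in replicate 2 and 6 against 88.8 in replicate 1, which argues against proportional carry-over of independent reads. Carry-over of a few amplified fragments and low expression in these roots stay open, since neither was tested.

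Single libraries held 854 values of 0 at 712 loci where the other 2 libraries of the group had at least 20 counts each, at 0.115% to 1.06% of such loci per library. Counting noise and replicate spread are argued against, since a negative binomial at 2 times the common coefficient of variation gave 33.1. Reads given to the next locus are argued against for most of the values of 0, since the next locus gained at least 50% of the missing level beside 12.8% of these values, against 8.43% at matched loci. A step of the authors' quantification that returns 0 for some loci may be the source, which was not tested, and no biological explanation was tested.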

How the results depend on the processing

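Alternatives without loci with an isolated 0, without identifiers of another format, without loci called in GUS roots in the scaling, without the 2 libraries apart on components 2 and 3, and adjusted over the list alone were chosen after seeing the data; the others were fixed before the data were examined. The inoculation-specific loci, the lists of called loci and the sets of loci raised or fallen in GUS roots were defined after seeing the data, so no alternative for them was fixed beforehand. Over the alternatives for named loci, 447 values kept their direction and their side of the threshold, 63 kept their direction alone, and 0 changed direction. Named loci were chosen for large changes without overlap between groups, so the kept directions follow in large part from this choice. The cause of the changes below was not tested, except that a threshold of 0.01 lowers counts by construction.

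Inoculation of GUS roots gave 675 loci at a threshold of 0.01 and 897 to 1563 without 1 library each. Inoculation of MtCLE35 roots gave 548 with DESeq2, 532 with DESeq2 without loci with an isolated 0, 1 at 0.01, 18 with the 2 groups alone, 15 thinned, 2 without the 2 libraries apart and 2 to 13 without 1 library. MtCLE35 against GUS at 11 dpi gave 438 at 0.01, 610 without the 2 libraries and 450 to 1034 without 1 library. Without rhizobia it gave 416 with DESeq2, 415 with DESeq2 without loci with an isolated 0, 6 at 0.01, 25 with the 2 groups alone, 9 without the 2 libraries, 27 without loci with an isolated 0 and 7 to 64 without 1 library. The interaction gave 987 with DESeq2, 985 with DESeq2 without loci with an isolated 0, 20 at 0.01, 61 with limma-voom, 23 without the 2 libraries, 181 without loci with an isolated 0 and 39 to 212 without 1 library.

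Adjusted over the list alone, loci called in GUS roots passed in MtCLE35 roots 183 times with DESeq2, 172 with DESeq2 without loci with an isolated 0, 9 without the 2 libraries and 11 to 67 without 1 library. Loci called at 11 dpi passed without rhizobia 75 times with DESeq2, 80 with DESeq2 without loci with an isolated 0, 31 with no low count filter, 29 without loci with an isolated 0 and 8 to 30 without 1 library. Inoculation-specific loci numbered 241 with limma-voom and 327 to 523 without 1 library. Without 1 library each, correlations between responses ran from -0.0654 to 0.0152 for inoculation and from -0.0927 to -0.00783 for the construct. Without 1 library each, the set of fallen loci had a camera p of 7.06e-15 to 0.47 and the set of raised expressed loci 7.91e-10 to 0.00285; with an estimated correlation and all libraries these were 0.0111 and 0.0168.

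Replicate numbers do not pair the libraries: residuals of libraries with the same number correlated at -0.078 to 0.069 over 18 pairs. A block on the replicate number gave 37 loci without rhizobia, 61 for the interaction and 74 for the list of loci called in GUS roots tested in MtCLE35 roots. With this block the interaction calls of MtrunA17Chr1g0171011.8, MtrunA17Chr5g0438201.4 and MtrunA17Chr4g0064831.4 were lost (adjusted p = 0.0598, 0.0833 and 0.0685). Not run were transcripts as deposited (each locus had 1 entry), scaling without nodule gene families, gene list and product family tests, and the overexpressed gene MtCLE35, all of which need gene names. At this depth 28% of simulated 2-fold changes were recovered, so a locus that was not called may still have changed.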

Other observations

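DESeq2 was fixed before the data were examined; the comparison of its calls between root types or states and the other tests in this part were chosen only after the results were seen.

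Inoculation-specific loci lay next to each other more often than a random placement gives. In the order of identifier numbers on the 8 chromosomes, 136 of 473 such loci were followed by another, against 11.4 expected (5 to 18 in 95% of permutations; one-sided permutation p = 1e-05, the smallest these permutations can give), and the longest run held 7 loci. All 1210 raised loci in this order gave 253 such pairs against 70.2 expected (p = 1e-05), and the 350 fallen loci gave 13 against 5.83 (permutation p = 0.0062). Reads shared between neighbouring copies were not separated from expression of each.

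With at least 10 counts in each library of a group and 0 in the other 9 libraries, 381 loci were found for GUS roots at 11 dpi, 1 for MtCLE35 roots at 11 dpi and 0 for either uninoculated group. The single locus was MtrunA17Chr7g0263981.4. The nearest well-covered locus before it by identifier was at 58.1 CPM ± 12.1 in MtCLE35 roots at 11 dpi and 61.3 CPM ± 14.9 in the other 9 libraries, and the nearest one after it at 10.8 CPM ± 3.09 and 22.4 CPM ± 5.67 (SD, n = 3 and 9). These CPM values use library totals without TMM scaling, and loci with few counts were passed over.

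DESeq2 called 396 loci higher and 152 lower after inoculation of MtCLE35 roots, and 69.7% and 82.9% of them had the same direction in GUS roots, a comparison that shares no library. Of its calls without rhizobia, 162 higher and 254 lower, 50.6% and 53.9% had the same direction at 11 dpi.

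MtrunA17Chr2g0325381.4 was the 1 locus at least 3-fold higher in each of the 6 MtCLE35 libraries than in any of the 6 GUS libraries, and 0 loci showed the reverse. A hypothesis is that its counts may include transcripts of the MtCLE35 construct. Finding 1 such locus cannot decide this, since MtCLE35 was not looked up by name and a locus that responds to the peptide would look alike.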
